A study of Homo sapiens with 24 samples.

How the data were processed

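Libraries were made from cells seeded overnight in 6-well plates and exposed to Piezo-CAP for 60 s or left untreated (0 s), with RNA taken at 24 h, per the labels' protocols. The medium was DMEM with 10% serum, or MEM for Fadu, RNA was extracted with Trizol and libraries were made with a SMARTER mRNA-Seq kit and sequenced on a HiSeq3000, per the labels' protocols. The reads were aligned with HISAT2 to GRCh38, per the submitters' processing notes. The version of HISAT2, the counting tool, the annotation release, the use of strand and the gene lengths behind TPM are not given in the sources used here. For each cell line the authors deposited a table of raw counts per gene and a table of TPM, each with 61533 genes. The deposited TPM equal the deposited counts divided by 1 length per gene and rescaled to the same total per library, to a relative departure of at most 9.3e-15. No other value was supplied and no sample was left out.

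Of the 61533 versioned Ensembl identifiers, 61415 were named by a symbol table, 105 by GENCODE 29 and 13 by neither. GENCODE 29 held 35913 of them with the same version and gave 58356 a position. All 37 mitochondrial genes had 0 counts in every library, so the list of mitochondrially encoded mRNAs could not be tested and the share of mitochondrial reads, a sign of cell damage, is unknown. Total counts are given with the results. Libraries of the same group differed by more than counting error, with a chi-square per degree of freedom of 2.965 to 8.699, and the biological coefficient of variation was 5.25%, 5.12%, 5.07% and 6.17% in Cal27, A375, Fadu and Hth83.

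Counts were analysed in R 4.3.3 with edgeR 4.0.16, separately in each line, 3 treated against 3 untreated libraries. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the quasi-likelihood test with robust dispersion was adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05 and no fold minimum. In each line 52.7%, 57.9%, 58.6% and 57.2% of the genes tested in Cal27, A375, Fadu and Hth83 had untreated and treated libraries that did not overlap in CPM, against 10% by chance. All 24 libraries were also fitted together as 8 group means, with an F test of the line by treatment interaction and a test of the mean of the 4 treatment effects. Overlaps between lines were tested by two-sided Fisher's exact tests over genes tested in both lines, 24 tests adjusted together.

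Gene lists, 37 of them with 1039 symbols, a panel of 26 genes, the tests and the first set of alternatives were chosen before the data were examined. Of the symbols 1038 were found, and LOR was not. Lists with at least 3 tested members were compared with all other genes by camera of limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the lists of a line, with camera at an estimated correlation and fry beside it. Fry tests whether the members move, on balance, one way and does not compare them with other genes. The genes named per line were, among those with an adjusted p under 0.05, at least 10 CPM in the higher group, a symbol that is not a clone name and no overlap between groups, the 8 with the largest rise and the 8 with the largest fall, then the 2 members with the smallest p of each called list, and the panel. For the joint tests they were the 10 genes with the smallest p. Not every gene so chosen is reported here. The lineage markers named were chosen from the fixed lists after their values were seen.

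The alternatives were DESeq2 1.42.0, RLE size factors, library size only, no or a stricter low-count filter (CPM of 1), no robust dispersion, a replicate block, the joint fit, a minimum fold, limma on log2(TPM + 1) with a filter (TPM of 1 in 3 libraries) or none and on log2(TPM + 0.1), and each library left out. Removal of a loess trend with gene length and GC, cameraPR after it, and list medians on TPM and library size, also relative to the other genes, were added after seeing the data. Intervals of list medians are 95% bootstrap intervals over the members (2000 draws). edgeR, DESeq2, limma on log2(TPM + 1), the joint tests and camera at its preset correlation were tested on simulated data with known changes, whereas fry, camera with an estimated correlation, the removal of the length and GC trend and the overlap tests were not. edgeR recovered 81.4%, 78.5%, 83% and 76.7% of genes changed 2-fold and 26.4%, 35.3%, 24.2% and 45.8% of those changed 1.2-fold in the simulations of Cal27, A375, Fadu and Hth83 (16732, 19155, 18440 and 16817 genes tested), with 1.4%, 3.5%, 3.82% and 2.13% of calls false. The interaction test recovered 81.8% of 2-fold changes in 1 line (22609 genes) and the mean test 96.7% of common ones (22624 genes). Camera called the planted list in each of the 4 simulations and 0 of 35 random lists, in libraries whose genes were drawn independently.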

Results

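RNA was sequenced from 4 human cancer cell lines 24 h after 60 s of Piezo-CAP and from untreated (0 s) wells of the same lines. Piezo-CAP is a cold atmospheric plasma, a partly ionised gas that stays near room temperature, made by a piezoelectric device. Cal27 is a line from a squamous cell carcinoma of the tongue, Fadu from a squamous cell carcinoma of the hypopharynx, Hth83, by its name, from an anaplastic thyroid carcinoma and A375 from a melanoma, although the labels count all 4 as head and neck cancer cells. The series title gives the purpose as sensitising head and neck cancer to chemotherapy and to immune checkpoint blockade. Each line had 3 untreated and 3 treated libraries, 24 libraries in 8 groups. Total counts, in M (mega), were 27.9 to 30.1 M in the untreated and 32.3 to 35.6 M in the treated libraries of Cal27 and 29.3 to 49.5 M in the untreated and 30.3 to 43.6 M in the treated libraries of A375. In the 2 other lines they were 30.7 to 37.5 M in the untreated and 29 to 35.3 M in the treated libraries of Fadu and 29.8 to 37.9 M in the untreated and 30.9 to 34.9 M in the treated libraries of Hth83. Between 24771 and 30823 genes had a count in a library, 96.8% to 97.89% of counts fell on protein-coding genes, and the 10 most abundant genes took 3.66% to 6.51%. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

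The value after a gene name is its log2 fold change, treated against untreated, ± SE with n = 3 libraries per group, and the value after a gene list is the median over its tested members. Rose and fell are used of genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test. Positions are those of GENCODE 29 on GRCh38. Counts of HSPA1A and HSPA1B, AKR1C1, KRT6A, KRT17, the HLA genes, the metallothioneins and the ribosomal protein genes are uncertain, because their reads can also align to near-identical genes or pseudogenes, and so are those of KCNQ1OT1 and MIR210HG, which overlap other transcripts, since the use of strand in counting is not given in the sources used here.

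Lineage markers differed between the lines. SOX10, a transcription factor of the melanocyte lineage, stood at 1070 ± 18.5 CPM in untreated A375 and at 0.0243 ± 0.0421 CPM, 0.0586 ± 0.0759 CPM and 0.0216 ± 0.0191 CPM in untreated Cal27, Fadu and Hth83. The pigment genes PMEL and MLANA were only at 1.12 ± 0.0348 CPM and 0.891 ± 0.0989 CPM in A375. PAX8, a thyroid transcription factor, was at 136 ± 0.83 CPM in untreated Hth83 and 23.6 ± 2.33 CPM in untreated Cal27, whereas thyroglobulin (TG) was at 0.0433 ± 0.0383 CPM in Hth83. TP63, the master regulator of squamous epithelium, was at 363 ± 23.6 CPM in Cal27, 421 ± 8.94 CPM in Fadu, 414 ± 13.2 CPM in Hth83 and 0.0128 ± 0.0223 CPM in A375. Of 18 squamous epithelium markers, 16 were over 10 CPM in untreated Hth83 (median 226 CPM), 14 in Cal27 (238 CPM) and 17 in Fadu (267 CPM), whereas of 16 thyroid markers 1, PAX8, was over 10 CPM in Hth83 (median 0.0196 CPM). These markers leave the identity of the Hth83 libraries in doubt, and the name is used as the labels give it. The median of 18 leukocyte markers was at most 0.0488 CPM in every group.

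The 4 comparisons within a line asked which transcripts differed 24 h after plasma exposure. In Cal27, interferon-stimulated genes, the antiviral effectors induced by interferon, fell: 46 of 47 fell and 1 did not pass (median -0.81, camera adjusted p = 1.95e-91). ISG15, a ubiquitin-like protein, went from 681 ± 39.1 to 273 ± 6.62 CPM (-1.32 ± 0.04), and MX2 (-1.33 ± 0.04), RSAD2 (-1.61 ± 0.06) and IFIT1 (-1.07 ± 0.05) fell with it. Of the NF-kB driven cytokines and inflammatory genes, 28 of 32 fell, 1 rose and 3 did not pass (median -0.59, camera adjusted p = 1.31e-33). IL6 (-1.42 ± 0.05), IL1B (-1.01 ± 0.03) and CXCL8 (-1.07 ± 0.11) were among those that fell. Genes of MHC class I antigen presentation also fell: 15 of 19 fell, 1 rose and 3 did not pass (median -0.52, camera adjusted p = 2.51e-13), HLA-C (-0.51 ± 0.03), HLA-F (-0.82 ± 0.05) and B2M (-0.34 ± 0.03) among them. Of the immune checkpoint ligands and regulators, 11 of 19 fell, 2 rose and 6 did not pass (median -0.32, camera adjusted p = 0.00247, adjusted p = 0.131 with an estimated correlation), including LGALS9 (-1.45 ± 0.10) and PVR (-0.37 ± 0.03), and CD274 (-0.57 ± 0.06), which encodes PD-L1, fell too. B2M was at -0.10 on log2(TPM + 1) and without a filter missed the threshold there (adjusted p = 0.127), with a range over all alternatives of 3.14e-29 to 0.127.

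NRF2 targets, the genes of the oxidative stress response, rose in Cal27: 19 of 27 rose, 3 fell and 5 did not pass (median 0.40, camera adjusted p = 1.59e-14). SLC7A11, the cystine transporter, went from 296 ± 4.79 to 626 ± 24.4 CPM (1.08 ± 0.04), and TXNRD1 (0.71 ± 0.03), NQO1 (0.59 ± 0.04) and HMOX1 (0.45 ± 0.10) rose as well. Of the mitosis and G2/M genes 32 of 49 rose, 2 fell and 15 did not pass (median 0.28, camera adjusted p = 2.27e-11). ASPM (0.99 ± 0.05) and MKI67 (0.63 ± 0.04) rose. Of the double-strand break repair genes 25 of 47 rose, 6 fell and 16 did not pass (median 0.21, camera adjusted p = 3.57e-05). ATM (0.97 ± 0.06) and PRKDC (0.71 ± 0.04) rose, 2 genes of DNA damage kinases. Genes of the integrated stress response downstream of ATF4 fell: 19 of 28 fell, 5 rose and 4 did not pass (median -0.29, camera adjusted p = 1.85e-07). PPP1R15A (-0.83 ± 0.03) and CHAC1 (-1.01 ± 0.05) fell. The endoplasmic reticulum chaperone and unfolded protein response list fell, 13 of 21 fell, 4 rose and 4 did not pass (median -0.30, camera adjusted p = 3.88e-05). HSPA5 (-0.62 ± 0.03) and CALR (-0.52 ± 0.03) fell. So did p53 targets, 13 of 28 fell, 5 rose and 10 did not pass (median -0.13, camera adjusted p = 6.53e-05), although their median was 0.08 on the deposited TPM (-0.12 relative to the other genes). GDF15 (-1.18 ± 0.04) and GADD45A (-1.06 ± 0.04) fell.

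Cytosolic ribosomal proteins fell in Cal27 by a small amount in nearly every member: 49 of 50 fell and 1 did not pass (median -0.37, camera adjusted p = 4.95e-25). RPLP2 (-0.49 ± 0.03) and RPS12 (-0.50 ± 0.04) fell. Nuclear-encoded subunits of oxidative phosphorylation did likewise, 47 of 54 fell and 7 did not pass (median -0.32, camera adjusted p = 2.27e-11). NDUFS8 (-0.50 ± 0.04) and ATP5F1D (-0.52 ± 0.05) fell. Squamous epithelium markers fell, 10 of 17 fell, 2 rose and 5 did not pass (median -0.43, camera adjusted p = 4.18e-10). The basal keratin KRT5 (-1.34 ± 0.04) and S100A2 (-0.69 ± 0.04) fell. Of the matrix and epithelial-mesenchymal transition genes 19 of 34 fell, 4 rose and 11 did not pass (median -0.21, camera adjusted p = 8.36e-05, adjusted p = 0.119 with an estimated correlation). PLAU (-0.73 ± 0.03) and SPARC (-0.62 ± 0.04) fell. Of YAP and TEAD targets 12 of 22 fell, 6 rose and 4 did not pass (median -0.23, camera adjusted p = 0.000241, adjusted p = 0.103 with an estimated correlation). CCN1 (-0.64 ± 0.03) and IGFBP3 (-0.60 ± 0.03) fell. For keratinocyte differentiation 10 of 19 fell, 3 rose and 6 did not pass (median -0.55, camera adjusted p = 0.00573, adjusted p = 0.154 with an estimated correlation). KRT17 (-1.63 ± 0.07) and KRT6A (-0.79 ± 0.08) fell. For fibroblast markers 5 of 8 fell, 1 rose and 2 did not pass (median -0.45, camera adjusted p = 0.00668, adjusted p = 0.1 with an estimated correlation). The complement proteases C1R (-1.03 ± 0.05) and C1S (-0.56 ± 0.05) fell. Further lists were lower than the other genes in Cal27 but had a median of the other sign on TPM, which raised the median of all genes of this line. Among immediate early genes 16 of 30 fell, 6 rose and 8 did not pass (median -0.23, camera adjusted p = 0.00619, adjusted p = 0.1 with an estimated correlation), with a median of 0.01 on TPM (-0.19 relative to the other genes), although FOSB (2.09 ± 0.07) and FOS (0.95 ± 0.05) rose. Antioxidant enzymes were lower, 14 of 21 fell, 3 rose and 4 did not pass (median -0.18, camera adjusted p = 0.00666, adjusted p = 0.129 with an estimated correlation), with a median of 0.06 on TPM (-0.14 relative to the other genes). GPX1 (-0.61 ± 0.05) and PRDX5 (-0.52 ± 0.04) fell. Ribosome biogenesis genes were lower, 20 of 34 fell, 6 rose and 8 did not pass (median -0.15, camera adjusted p = 0.00748, adjusted p = 0.1 with an estimated correlation), with a median of 0.08 on TPM (-0.12 relative to the other genes). SRM (-0.52 ± 0.04) and BOP1 (-0.46 ± 0.04) fell. Autophagy and lysosome genes were lower, 18 of 34 fell, 6 rose and 10 did not pass (median -0.14, camera adjusted p = 0.0242, adjusted p = 0.103 with an estimated correlation), with a median of 0.08 on TPM (-0.12 relative to the other genes). MAP1LC3B (-0.69 ± 0.04) and CTSB (-0.40 ± 0.03) fell. Calls were lost by autophagy with a stricter low-count filter (adjusted p = 0.0518) and with library size only (0.101), by ribosome biogenesis with library size only (0.0698) and by immediate early genes after a trend with gene length and GC was removed (0.137), with ranges over the camera alternatives of 0.0193 to 0.103, 0.00362 to 0.1 and 0.00284 to 0.137. Adjusted over the list alone, the counts of members were the same for the called lists of Cal27 except that 20 rose and 3 fell among NRF2 targets, 6 rose and 19 fell in the ATF4 list, 5 rose and 13 fell in the endoplasmic reticulum list, 27 rose and 7 fell among double-strand break repair, 6 rose and 19 fell among autophagy and lysosome, 0 rose and 49 fell among oxidative phosphorylation and 7 rose and 14 fell among YAP and TEAD targets.

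FST, the activin antagonist follistatin (ENSG00000134363.12, chromosome 5, 53480409 to 53487134, plus strand), fell most among the genes above 10 CPM in Cal27 whose groups did not overlap, from 718 ± 11.9 to 182 ± 3.44 CPM (log2 fold change -1.98 ± 0.03, adjusted p = 4.29e-29). FOSB, a subunit of the AP-1 transcription factor (ENSG00000125740.14, chromosome 19, 45467995 to 45475179, plus strand), rose most, from 23.4 ± 2.6 to 99.6 ± 8.2 CPM (adjusted p = 4.51e-18). The other large falls were in the death ligand TNFSF10 (-1.54 ± 0.09), the chemokine CXCL11 (-1.45 ± 0.10), the collagenase MMP13 (-1.76 ± 0.15) and CMPK2 (-1.47 ± 0.08). The other large rises were in the pseudogene NMRAL2P (1.86 ± 0.06), the aldo-keto reductase AKR1C1 (1.78 ± 0.08), the NF-kB subunit REL (1.46 ± 0.11), the NKp30 ligand NCR3LG1 (1.36 ± 0.10), KCNQ1OT1 (1.49 ± 0.14), GPR135 (1.40 ± 0.12) and GVQW3 (1.28 ± 0.11). Of the 26 genes fixed before the data were examined, 10 rose, 13 fell and 3 did not pass, with 11 and 13 adjusted over the list alone. Those that fell included TRIB3 (-0.63 ± 0.04), DDIT3 (-1.08 ± 0.06), ATF3 (-0.65 ± 0.05), CXCL10 (-1.45 ± 0.08) and CDKN1A (-0.59 ± 0.04), and those that rose included HSPA1A (0.83 ± 0.07) and BRCA1 (0.56 ± 0.05). EGR1 (0.12 ± 0.04) and CCNB1 (0.10 ± 0.04) passed narrowly, with adjusted p of 0.0613 for EGR1 without treated replicate 2 and 0.31 in the joint fit of all 24 libraries, and for CCNB1 of 0.129 without untreated replicate 3, 0.0662 without treated replicate 2, 0.126 without treated replicate 3 and 0.0557 in the joint fit. Over all alternatives the adjusted p ran from 1.86e-05 to 0.31 for EGR1 and 0.00017 to 0.129 for CCNB1.

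By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7832 of 17371 genes tested in Cal27 passed, 3801 higher and 4031 lower. Of those, 617 differed by at least 2-fold (422 higher and 195 lower), and the median size of the log2 change among all that passed was 0.36. Camera called 21 of 36 gene lists in Cal27, 3 higher and 18 lower, and 12 of the calls held with an estimated correlation. Camera did not call the other 15 lists tested in Cal27, the closest of which had an adjusted p of 0.0501. Among them were heat shock proteins (0.06), DNA replication and G1/S (-0.02), base and nucleotide excision repair (-0.10), BCL2 family and caspases (-0.10) and ferroptosis regulators (0.07), with the median in parentheses. The rest included cholesterol biosynthesis (-0.03), fatty acid synthesis (0.12), hypoxia and glycolysis (0.04), metallothioneins (-0.30) and platinum and drug transport (0.02). They also included epithelial junctions (-0.08), melanocyte markers (0.62), thyroid follicle markers (0.06), leukocyte markers (-0.02) and endothelial markers (-0.43). Of these, the median, the mean and the test did not share a sign for DNA replication and G1/S, cholesterol biosynthesis, thyroid follicle markers and leukocyte markers. The BCL2 list passed, lower, after a trend with gene length and GC was removed (adjusted p = 0.0341) and without untreated replicate 1 (0.0326) or 2 (0.0349) or treated replicate 2 (0.0428) or 3 (0.0238), metallothioneins passed, lower, without untreated replicate 1 (0.0265) or treated replicate 1 (0.0135), and with library size only heat shock proteins (0.0109) and hypoxia genes (0.036) passed, higher, the former also after the trend was removed (0.0416). Their ranges over the camera alternatives were 0.0238 to 0.129, 0.0135 to 0.442, 0.0109 to 0.145 and 0.036 to 0.496. The direction of small changes in Cal27 depends on the scaling. Of the genes that passed, 48.5% were higher, against 62.4% with library size only and 83.4% on log2(TPM + 1), which moved the median of all genes by 0.082 and 0.224. Medians of called lists moved with it: on TPM, alone and relative to the other genes, they were 0 and -0.20 for YAP and TEAD targets, -0.03 and -0.23 for epithelial-mesenchymal transition and matrix genes, -0.06 and -0.26 for fibroblast markers, -0.05 and -0.25 for immune checkpoint ligands, -0.06 and -0.25 for the ATF4 list and -0.07 and -0.26 for the endoplasmic reticulum list. They were -0.28 and -0.48 for MHC class I antigen presentation, -0.35 and -0.55 for NF-kB driven inflammatory genes, -0.08 and -0.28 for oxidative phosphorylation, -0.14 and -0.34 for cytosolic ribosomal proteins, -0.34 and -0.54 for keratinocyte differentiation, -0.19 and -0.39 for squamous epithelium markers, 0.46 and 0.27 for mitosis and G2/M and 0.42 and 0.22 for double-strand break repair, of which mitosis and double-strand break repair were at 0.16 and 0.11 after the trend with length and GC was removed.

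**Figure D1:**
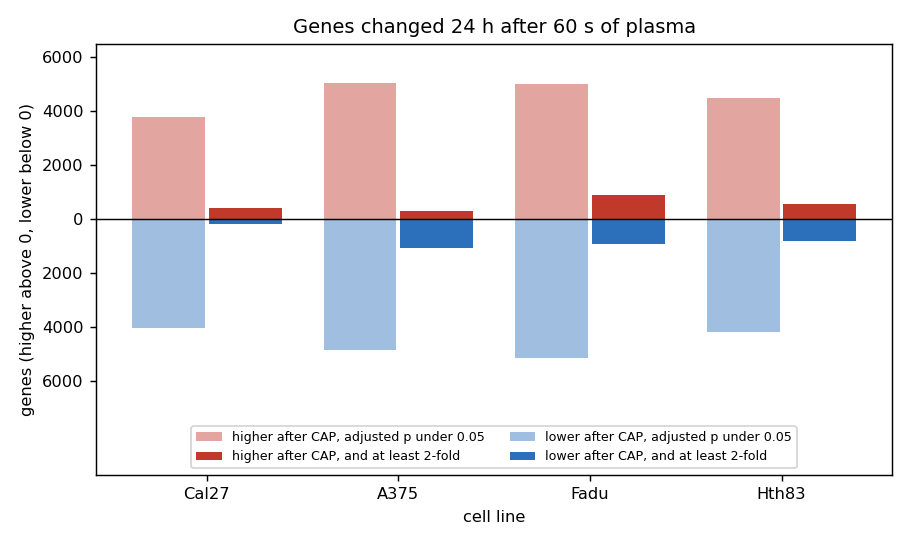
Genes that passed in each cell line, with the number of genes on the vertical axis, those higher after plasma drawn above 0 and those lower drawn below. Pale bars count all genes with an adjusted p under 0.05 and dark bars those that also changed at least 2-fold, from 617 in Cal27 to 1814 in Fadu.

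In A375, genes of the integrated stress response downstream of ATF4 fell: 25 of 27 fell and 2 did not pass (median -0.90, camera adjusted p = 2.66e-43, adjusted p = 0.199 with an estimated correlation). DDIT3, the stress transcription factor CHOP, went from 29.6 ± 3.78 to 6.35 ± 0.792 CPM (-2.23 ± 0.10), and CHAC1 (-2.62 ± 0.08), ASNS (-2.62 ± 0.11), TRIB3 (-1.45 ± 0.08), ATF3 (-2 ± 0.12) and DDIT4 (-1.10 ± 0.04) fell, ASNS being asparagine synthetase. Heat shock proteins rose, 22 of 25 rose, 1 fell and 2 did not pass (median 0.65, camera adjusted p = 3.83e-34, adjusted p = 0.199 with an estimated correlation). HSPA1A (2.67 ± 0.11), HSPA1B (2.56 ± 0.10) and HSPH1 (1.21 ± 0.04) rose, and the constitutive chaperone HSPA8 rose from 811 ± 47.2 to 2700 ± 262 CPM (1.73 ± 0.08). Genes of DNA replication and G1/S rose too, 46 of 51 rose, 1 fell and 4 did not pass (median 0.42, camera adjusted p = 1.07e-21, adjusted p = 0.199 with an estimated correlation). PCNA (1.03 ± 0.04) and UHRF1 (1.01 ± 0.05) rose. Of the hypoxia and glycolysis genes, 24 of 35 fell, 7 rose and 4 did not pass (median -0.33, camera adjusted p = 1.88e-14, adjusted p = 0.199 with an estimated correlation). The carbonic anhydrase CA9 (-5.51 ± 0.16) and the glucose transporter SLC2A3 (-1.28 ± 0.05) fell.

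The endoplasmic reticulum chaperone list rose in A375, 15 of 21 rose, 3 fell and 3 did not pass (median 0.31, camera adjusted p = 3.07e-07, adjusted p = 0.32 with an estimated correlation). HSPA5 (0.71 ± 0.03) and CALR (0.61 ± 0.03) rose. Ribosome biogenesis genes rose, 31 of 34 rose and 3 did not pass (median 0.42, camera adjusted p = 5.82e-18, adjusted p = 0.302 with an estimated correlation). NOP56 (0.82 ± 0.04) and NOLC1 (0.69 ± 0.03) rose. So did NRF2 targets, 18 of 27 rose, 3 fell and 6 did not pass (median 0.30, camera adjusted p = 4.55e-07, adjusted p = 0.359 with an estimated correlation). NQO1 (0.72 ± 0.04), PRDX1 (0.80 ± 0.04), TXNRD1 (0.66 ± 0.04) and HMOX1 (1.08 ± 0.12) rose. SLC7A11 (-1 ± 0.08) fell. For nuclear-encoded oxidative phosphorylation 36 of 54 rose, 3 fell and 15 did not pass (median 0.18, camera adjusted p = 0.000427, adjusted p = 0.421 with an estimated correlation). ATP5MC3 (0.44 ± 0.04) and UQCRFS1 (0.39 ± 0.04) rose. For mitosis and G2/M 28 of 49 rose, 6 fell and 15 did not pass (median 0.14, camera adjusted p = 0.000749, adjusted p = 0.505 with an estimated correlation). CDC20 (0.52 ± 0.04) and FOXM1 (0.58 ± 0.04) rose. For double-strand break repair 23 of 47 rose, 5 fell and 19 did not pass (median 0.14, camera adjusted p = 0.00767, adjusted p = 0.432 with an estimated correlation). H2AX (0.64 ± 0.04) rose. Of the p53 targets 16 of 27 rose, 7 fell and 4 did not pass (median 0.29, camera adjusted p = 0.0202, adjusted p = 0.55 with an estimated correlation), among them PLK2 (1.02 ± 0.07) and CDKN1A (0.91 ± 0.13) and, in the other direction, SESN2 (-1.42 ± 0.07). The p53 call was lost with a stricter low-count filter (adjusted p = 0.0583) and after a trend with gene length and GC was removed (0.0631), with a range over the camera alternatives of 0.00418 to 0.55. The epithelial-mesenchymal transition and matrix list fell narrowly, 14 of 33 fell, 6 rose and 13 did not pass (median -0.09, camera adjusted p = 0.0399, adjusted p = 0.302 with an estimated correlation). TNC (-0.39 ± 0.03) and COL4A2 (-0.39 ± 0.03) fell. Its call was lost without untreated replicate 2 (adjusted p = 0.0572), treated replicate 2 (0.0709) or treated replicate 3 (0.0586), with a range over the camera alternatives of 0.0121 to 0.302. Adjusted over the list alone, the counts of members were the same for the called lists of A375 except that 18 rose and 4 fell among NRF2 targets, 18 rose and 7 fell among p53 targets, 16 rose and 3 fell in the endoplasmic reticulum list, 29 rose and 6 fell among mitosis and G2/M and 47 rose and 1 fell among DNA replication and G1/S.

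CA9 (ENSG00000107159.14, chromosome 9, 35673856 to 35681159, plus strand) fell most among the genes above 10 CPM in A375, from 22.6 ± 2.39 to 0.502 ± 0.102 CPM (log2 fold change -5.51 ± 0.16, adjusted p = 3.95e-22). TXNIP, the thioredoxin-interacting protein whose transcription follows glucose (ENSG00000265972.6, chromosome 1, 145992435 to 145996600, minus strand), fell from 199 ± 9.89 to 17.5 ± 2.1 CPM (-3.51 ± 0.06, adjusted p = 3.33e-24). The other large falls were in the hypoxia-induced transcript MIR210HG (-3.54 ± 0.21), the peptide hormone ADM2 (-3.36 ± 0.11) and the chloride channel BEST1 (-2.80 ± 0.14). TFRC, the transferrin receptor (ENSG00000072274.13, chromosome 3, 196027183 to 196082189, minus strand), rose from 70.9 ± 3.59 to 359 ± 28.8 CPM (2.33 ± 0.05, adjusted p = 8.46e-21), and other large rises were in WNT9A (2.35 ± 0.20) and ENC1 (2.20 ± 0.17), the Wnt antagonist DKK1 (1.90 ± 0.12) and the neurotrophin receptor NGFR (1.82 ± 0.14). Of the 26 fixed genes, 24 were tested in A375, and 13 rose, 8 fell and 3 did not pass, with the same counts adjusted over the list alone. Of the immune genes among them, IFIT1 (0.44 ± 0.11) and B2M (0.13 ± 0.03) rose and CXCL8 (-0.16 ± 0.06) fell, while CD274 was at 0.22 ± 0.17 (adjusted p = 0.282). Calls were lost by B2M with library size only (adjusted p = 0.129) and on log2(TPM + 1) (0.254) and by CXCL8 with DESeq2 (0.0631), in the joint fit (0.318), on log2(TPM + 1) without a filter (0.0544) and without untreated replicate 1 (0.221) or 2 (0.0518) or treated replicate 3 (0.218). Over all alternatives the adjusted p ran from 3.63e-05 to 0.453 for B2M and 0.00361 to 0.318 for CXCL8.

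By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9900 of 19604 genes tested in A375 passed, 5044 higher and 4856 lower. Of those, 1385 differed by at least 2-fold (304 higher and 1081 lower), and the median size of the log2 change among all that passed was 0.42. Camera called 12 of 35 lists in A375, 9 higher and 3 lower, and 0 of the calls held with an estimated correlation (5 lists at an unadjusted p under 0.05), while fry, which tests a list by itself, called 22. Camera did not call the other 23 lists tested in A375, the closest of which had an adjusted p of 0.112. Among them were antioxidant enzymes (0.24), interferon-stimulated genes (0.01), MHC class I antigen presentation (0.03), immune checkpoint ligands (0.04), NF-kB driven inflammatory genes (0.05), immediate early genes (0.14), base and nucleotide excision repair (0.02) and BCL2 family and caspases (0.16), with the median in parentheses. The rest included ferroptosis regulators (0.13), autophagy and lysosome (0.11), cholesterol biosynthesis (0), fatty acid synthesis (-0.03), cytosolic ribosomal proteins (0.02), platinum and drug transport (0.11), epithelial junctions (-0.10) and YAP and TEAD targets (-0.06). They also included keratinocyte differentiation (-0.05), squamous epithelium markers (0.19), melanocyte markers (-0.03), thyroid follicle markers (0.31), fibroblast markers (-0.20), leukocyte markers (-0.56) and endothelial markers (-0.26). Of these, the median, the mean and the test did not share a sign for interferon-stimulated genes, fatty acid synthesis, keratinocyte differentiation and endothelial markers. Of the genes that passed in A375, 50.9% were higher, against 39.8% with library size only and 40.8% on log2(TPM + 1). On TPM the medians of called lists were 0.19 for p53 targets, 0.05 for mitosis and G2/M, 0.07 for double-strand break repair, 0.09 for oxidative phosphorylation and -0.17 for epithelial-mesenchymal transition and matrix genes.

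In Fadu, interferon-stimulated genes fell: 43 of 47 fell, 1 rose and 3 did not pass (median -0.95, camera adjusted p = 1.02e-48, adjusted p = 0.0938 with an estimated correlation). OAS2 (-1.85 ± 0.05), PARP14 (-1.11 ± 0.03) and IFIT1 (-1 ± 0.04) fell. NRF2 targets fell as well, 23 of 28 fell, 1 rose and 4 did not pass (median -0.78, camera adjusted p = 2.61e-23, adjusted p = 0.0938 with an estimated correlation). SLC7A11 went from 252 ± 5.25 to 89.7 ± 6.79 CPM (-1.49 ± 0.04), and HMOX1 (-1.42 ± 0.07), TKT (-0.81 ± 0.03), NQO1 (-0.59 ± 0.03) and TXNRD1 (-0.54 ± 0.03) fell. Genes of cholesterol synthesis and uptake fell, 20 of 24 fell, 1 rose and 3 did not pass (median -0.77, camera adjusted p = 1.4e-23, adjusted p = 0.09 with an estimated correlation). HMGCS1 (-1.29 ± 0.04) fell. So did fatty acid synthesis genes, 13 of 17 fell, 2 rose and 2 did not pass (median -0.39, camera adjusted p = 2.64e-11, adjusted p = 0.123 with an estimated correlation). ACACA (-0.83 ± 0.03) and FADS1 (-1.21 ± 0.04) fell. The ATF4 list fell, 25 of 28 fell, 1 rose and 2 did not pass (median -0.67, camera adjusted p = 1.68e-22, adjusted p = 0.0926 with an estimated correlation). SLC7A5 (-0.77 ± 0.03), STC2 (-0.77 ± 0.03), DDIT3 (-1.64 ± 0.08) and ATF3 (-1.51 ± 0.08) fell. The endoplasmic reticulum list fell with it, 20 of 21 fell and 1 rose (median -0.61, camera adjusted p = 1.4e-23, adjusted p = 0.0947 with an estimated correlation). HSPA5 (-1.04 ± 0.03), SEL1L (-1.20 ± 0.04) and EDEM1 (-1.02 ± 0.04) fell. Matrix and epithelial-mesenchymal transition genes rose, 21 of 35 rose, 7 fell and 7 did not pass (median 0.56, camera adjusted p = 4.42e-08, adjusted p = 0.09 with an estimated correlation). The collagenase MMP1 (2 ± 0.05) rose.

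Keratinocyte differentiation genes fell in Fadu, 16 of 27 fell, 5 rose and 6 did not pass (median -0.92, camera adjusted p = 2.67e-06, adjusted p = 0.123 with an estimated correlation). Filaggrin (-2.79 ± 0.16) and transglutaminase 1 (-1.72 ± 0.08) fell. Squamous epithelium markers fell, 10 of 18 fell, 7 rose and 1 did not pass (median -0.42, camera adjusted p = 5.32e-07, adjusted p = 0.123 with an estimated correlation). PKP1 (-1.43 ± 0.05) and KRT14 (-0.77 ± 0.03) fell. Epithelial junction genes fell, 9 of 18 fell, 6 rose and 3 did not pass (median -0.10, camera adjusted p = 0.00216, adjusted p = 0.123 with an estimated correlation), although their median was 0.01 with library size only (-0.11 relative to the other genes). CLDN1 (-1.67 ± 0.04) and CDH1 (-0.71 ± 0.03) fell. Without untreated replicate 1 the medians of keratinocyte differentiation and epithelial junctions were -0.54 and -0.04. Of the hypoxia and glycolysis genes 29 of 35 fell, 3 rose and 3 did not pass (median -0.31, camera adjusted p = 6.51e-10, adjusted p = 0.133 with an estimated correlation). NDRG1 (-1.15 ± 0.03) and SLC2A1 (-0.88 ± 0.03) fell. Of the mitosis and G2/M genes 34 of 49 fell, 5 rose and 10 did not pass (median -0.31, camera adjusted p = 1.15e-08, adjusted p = 0.123 with an estimated correlation). CENPF (-1.05 ± 0.03), ASPM (-0.79 ± 0.03) and MKI67 (-0.56 ± 0.03) fell. For MHC class I antigen presentation 14 of 19 fell, 2 rose and 3 did not pass (median -0.29, camera adjusted p = 5.81e-06, adjusted p = 0.188 with an estimated correlation). ERAP2 (-1.16 ± 0.04), PSME1 (-0.79 ± 0.04) and B2M (-0.29 ± 0.03) fell. For fibroblast markers 4 of 6 fell, 1 rose and 1 did not pass (median -1.01, camera adjusted p = 2.67e-06, adjusted p = 0.123 with an estimated correlation). C1R (-2.73 ± 0.10) and FBLN1 (-0.95 ± 0.04) fell.

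Ribosome biogenesis genes rose in Fadu, 28 of 34 rose, 3 fell and 3 did not pass (median 0.33, camera adjusted p = 3.19e-10, adjusted p = 0.09 with an estimated correlation). ODC1 (1.44 ± 0.04) and NOP56 (0.67 ± 0.03) rose. So did cytosolic ribosomal proteins, 42 of 50 rose, 4 fell and 4 did not pass (median 0.18, camera adjusted p = 5.93e-06, adjusted p = 0.283 with an estimated correlation). RPS13 (0.57 ± 0.03) and RPL18 (0.44 ± 0.03) rose. Oxidative phosphorylation genes rose, 30 of 54 rose, 6 fell and 18 did not pass (median 0.16, camera adjusted p = 0.00699, adjusted p = 0.236 with an estimated correlation). NDUFB9 (0.57 ± 0.04) and ATP5MC1 (0.46 ± 0.05) rose. Of the immediate early genes 20 of 30 fell, 8 rose and 2 did not pass (median -0.43, camera adjusted p = 0.00152, adjusted p = 0.188 with an estimated correlation). CCN2 (-1.94 ± 0.06), FOS (-1.09 ± 0.03) and EGR1 (-0.97 ± 0.04) fell. FOSL1 (2.07 ± 0.04) rose. For ferroptosis regulators 16 of 25 fell, 6 rose and 3 did not pass (median -0.44, camera adjusted p = 0.00144, adjusted p = 0.188 with an estimated correlation), with SLC7A11 again and, in the other direction, LPCAT1 (0.97 ± 0.04). For autophagy and lysosome genes 14 of 35 fell, 6 rose and 15 did not pass (median -0.10, camera adjusted p = 0.0192, adjusted p = 0.123 with an estimated correlation). CTSD (-1.25 ± 0.04) and SQSTM1 (-0.56 ± 0.03) fell. Metallothioneins rose, 2 of 4 rose and 2 did not pass (median 0.09, camera adjusted p = 0.0113, adjusted p = 0.188 with an estimated correlation), although their median was -0.02 (adjusted p = 0.191) after a trend with gene length and GC was removed and 0.17 without untreated replicate 1. MT2A (1.31 ± 0.07) and MT1E (0.21 ± 0.05) rose. Calls were also lost by oxidative phosphorylation after that trend was removed (0.0552) and by autophagy with library size only (median 0, adjusted p = 0.0674), with ranges over the camera alternatives of 0.00143 to 0.191 for metallothioneins, 0.000407 to 0.236 for oxidative phosphorylation and 0.00612 to 0.123 for autophagy. Antioxidant enzymes fell narrowly, 12 of 21 fell, 7 rose and 2 did not pass (median -0.12, camera adjusted p = 0.0489, adjusted p = 0.409 with an estimated correlation). GPX2 (-1.51 ± 0.08) and GPX4 (-0.74 ± 0.05) fell. The list missed the threshold without untreated replicate 1 (adjusted p = 0.053) or treated replicate 2 (0.0784), with a stricter low-count filter (0.0922) and with library size only (median -0.02, adjusted p = 0.0877), with a range over the camera alternatives of 0.0118 to 0.409. Adjusted over the list alone, the counts of members were the same for the called lists of Fadu except that 1 rose and 26 fell in the ATF4 list and 31 rose and 6 fell among oxidative phosphorylation.

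IL1RL1, the receptor of interleukin 33 (ENSG00000115602.17, chromosome 2, 102311502 to 102352037, plus strand), rose most among the genes above 10 CPM in Fadu, from 4.3 ± 0.824 to 110 ± 5.56 CPM (log2 fold change 4.66 ± 0.07, adjusted p = 2.7e-58). TXNIP (ENSG00000265972.6, chromosome 1, 145992435 to 145996600, minus strand) rose from 16.4 ± 0.867 to 290 ± 14.1 CPM (4.14 ± 0.05, adjusted p = 2.01e-82), and its relative ARRDC4 (3.48 ± 0.08) rose with it. Other large rises were in the activin subunit INHBA (4.58 ± 0.14), the ion channel TRPV3 (4.11 ± 0.15), the cadherin CDH11 (3.63 ± 0.14), the stromelysin MMP3 (3.54 ± 0.14) and the lipoxygenase ALOXE3 (3.57 ± 0.16). The keratin KRT4 (ENSG00000170477.13, chromosome 12, 52806549 to 52814551, minus strand) fell most, from 134 ± 3.9 to 7.48 ± 6.03 CPM (-4.21 ± 0.47, adjusted p = 0.0017). The copper oxidase CP (-4.17 ± 0.37), the endothelin EDN2 (-3.17 ± 0.27), the mucin MUC16 (-3.03 ± 0.15), TNNT3 (-3.04 ± 0.17), HTRA3 (-2.96 ± 0.26) and ALDH3B2 (-2.93 ± 0.44) followed. In treated replicate 1, KRT4 stood at 14.41 CPM, against 4.64 and 3.39 CPM in the other treated libraries. Of the 26 fixed genes, 6 rose, 17 fell and 3 did not pass, with the same counts adjusted over the list alone. CD274 rose from 17.3 ± 2.13 to 36.6 ± 2.44 CPM (1.09 ± 0.08). CDKN1A (1.07 ± 0.05), CXCL8 (0.79 ± 0.04) and HSPA1A (0.66 ± 0.05) rose. GDF15 (-1.50 ± 0.05), CXCL10 (-3.67 ± 0.47), TRIB3 (-0.46 ± 0.05) and BRCA1 (-0.20 ± 0.04) fell. MCM2, at -0.12 ± 0.04, was at -0.01 with library size only (adjusted p = 0.765) and -0.05 without untreated replicate 1 (0.287) and missed the threshold in the joint fit (0.0614) and on log2(TPM + 1) (0.181). Over all alternatives the adjusted p ran from 0.00153 to 0.765 for MCM2.

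By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 10200 of 19152 genes tested in Fadu passed, 5031 higher and 5169 lower. Of those, 1814 differed by at least 2-fold (887 higher and 927 lower), and the median size of the log2 change among all that passed was 0.46. Camera called 22 of 36 lists in Fadu, 5 higher and 17 lower, and 0 of the calls held with an estimated correlation (14 lists at an unadjusted p under 0.05), while fry called 32. Camera did not call the other 14 lists tested in Fadu, the closest of which had an adjusted p of 0.075. Among them were p53 targets (-0.18), heat shock proteins (0.06), immune checkpoint ligands (-0.20), NF-kB driven inflammatory genes (0.08) and DNA replication and G1/S (0.10), with the median in parentheses. The rest included double-strand break repair (-0.05), base and nucleotide excision repair (0.05), BCL2 family and caspases (-0.18), platinum and drug transport (-0.08) and YAP and TEAD targets (0). They also included melanocyte markers (-0.25), thyroid follicle markers (-0.25), leukocyte markers (0.03) and endothelial markers (0.37). Of these, the median, the mean and the test did not share a sign for heat shock proteins, immune checkpoint ligands, leukocyte markers and endothelial markers. Of the genes that passed in Fadu, 49.3% were higher, against 61.8% with library size only, which moved the median of all genes by 0.105. With it the medians of called lists were -0.19 for MHC class I antigen presentation, 0.26 for oxidative phosphorylation, 0.28 for cytosolic ribosomal proteins and 0.19 for metallothioneins, and DNA replication genes, which camera called in no other setting, passed as higher (adjusted p = 0.00702, range over the camera alternatives 0.00702 to 0.236). Ferroptosis regulators were at -0.26 on TPM and -0.26 with a stricter low-count filter, and ribosomal proteins, autophagy and antioxidant genes at 0.10, -0.17 and -0.20 after the trend with length and GC was removed.

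**Figure D2:**
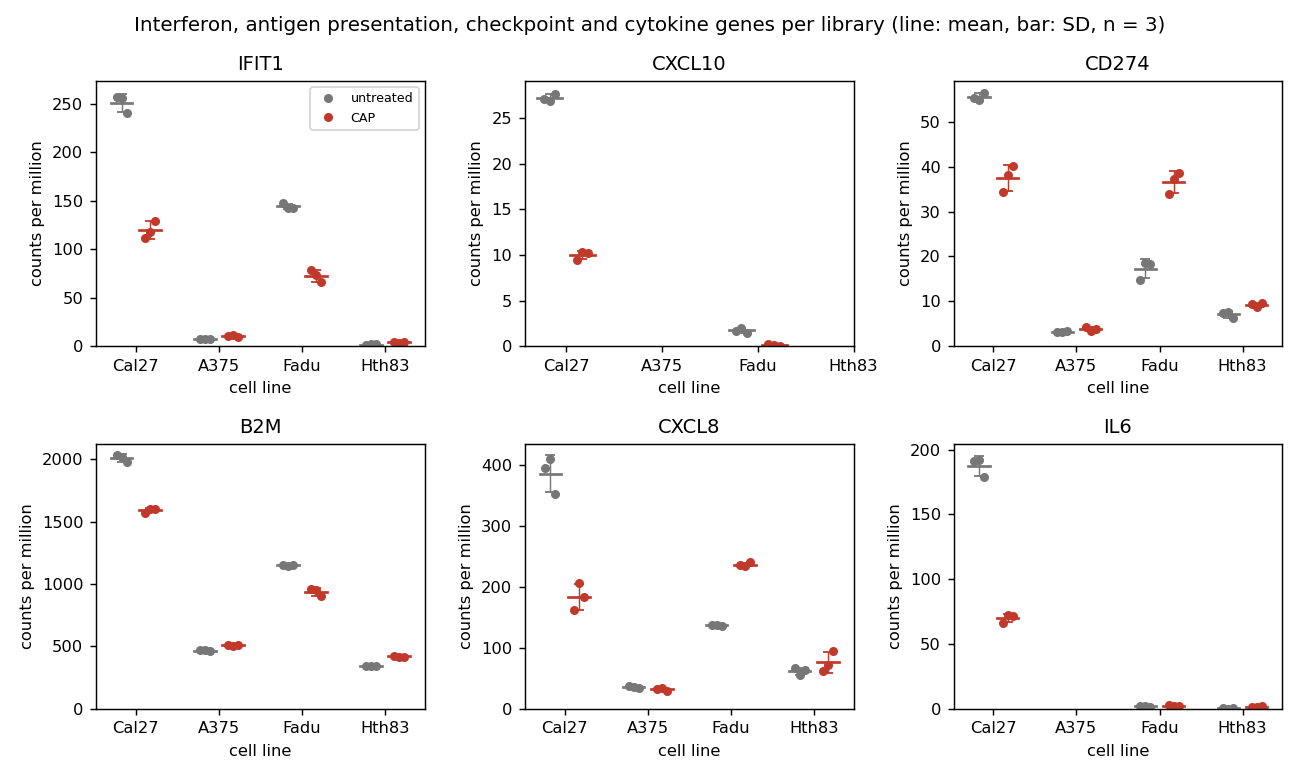
CPM of 6 interferon, antigen presentation, checkpoint and cytokine genes in each library, untreated in grey and plasma-treated in red, with a horizontal line at the mean and a bar for the SD (n = 3). No points are drawn for CXCL10 in A375 and Hth83 or for IL6 in A375, where these genes were not tested. IFIT1 and CXCL10 were lower after plasma in Cal27 and Fadu, and CD274 was lower in Cal27 and higher in Fadu.

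In Hth83, all tested endoplasmic reticulum chaperone and unfolded protein response genes fell: 22 of 22 fell (median -1.61, camera adjusted p = 7.28e-94). HSPA5, the chaperone BiP (ENSG00000044574.9, chromosome 9, 125234853 to 125241330, minus strand), went from 8450 ± 524 to 1150 ± 6.19 CPM (-2.88 ± 0.04, adjusted p = 3.95e-29), and HERPUD1, a component of endoplasmic reticulum degradation (ENSG00000051108.15, chromosome 16, 56932048 to 56944863, plus strand), from 543 ± 13.9 to 51.4 ± 1.82 CPM (-3.40 ± 0.05, adjusted p = 9.98e-30). The ATF4 list fell in parallel, 25 of 27 fell and 2 rose (median -1.42, camera adjusted p = 6.68e-60). DDIT3 (-4 ± 0.09), TRIB3 (-2.53 ± 0.05), ATF3 (-2.26 ± 0.12), CHAC1 (-4.46 ± 0.13) and ASNS (-4.71 ± 0.18) fell. Genes of DNA replication and G1/S rose, 50 of 51 rose and 1 fell (median 0.81, camera adjusted p = 1.54e-40, adjusted p = 0.185 with an estimated correlation). UHRF1 (1.89 ± 0.06), FEN1 (1.16 ± 0.05) and MCM2 (1.05 ± 0.05) rose. Mitosis and G2/M genes rose, 40 of 49 rose and 9 did not pass (median 0.50, camera adjusted p = 1.84e-18, adjusted p = 0.184 with an estimated correlation). ANLN (0.87 ± 0.05), CCNA2 (0.86 ± 0.05) and MKI67 (0.69 ± 0.04) rose. Heat shock proteins rose, 18 of 22 rose and 4 did not pass (median 0.84, camera adjusted p = 1.63e-21, adjusted p = 0.165 with an estimated correlation). HSPA1A (2.70 ± 0.13), HSPA1B (2.45 ± 0.10), HSPH1 (1.31 ± 0.05) and HSP90AA1 (1.08 ± 0.05) rose.

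Interferon-stimulated genes rose in Hth83, 21 of 38 rose, 5 fell and 12 did not pass (median 0.38, camera adjusted p = 0.00818, adjusted p = 0.322 with an estimated correlation). OAS3 (1.08 ± 0.05), IFIT5 (0.94 ± 0.08) and IFIT1 (1.37 ± 0.22) rose. Cholesterol synthesis genes rose on balance, 14 of 23 rose, 3 fell and 6 did not pass (median 0.35, camera adjusted p = 9.28e-05, adjusted p = 0.329 with an estimated correlation). STARD4 (-1.10 ± 0.06) fell, against the direction of the list. For double-strand break repair 28 of 47 rose, 4 fell and 15 did not pass (median 0.24, camera adjusted p = 9.28e-05, adjusted p = 0.322 with an estimated correlation). H2AX (1.01 ± 0.06), EXO1 (0.88 ± 0.06) and BRCA1 (0.61 ± 0.06) rose. For ribosome biogenesis 24 of 34 rose, 1 fell and 9 did not pass (median 0.30, camera adjusted p = 3.06e-05, adjusted p = 0.502 with an estimated correlation). NOP56 (0.66 ± 0.05) and NOLC1 (0.68 ± 0.05) rose. Cytosolic ribosomal proteins fell, 41 of 50 fell and 9 did not pass (median -0.22, camera adjusted p = 5.41e-06, adjusted p = 0.524 with an estimated correlation). RPL12 (-0.64 ± 0.04) and RPL3 (-0.48 ± 0.04) fell. Of the squamous epithelium markers 12 of 17 fell, 4 rose and 1 did not pass (median -0.22, camera adjusted p = 0.00262, adjusted p = 0.502 with an estimated correlation). ITGB4 (-0.90 ± 0.04) fell. KRT5 (0.60 ± 0.05) rose. The p53 target list was called lower, 10 of 27 fell, 10 rose and 7 did not pass (median -0.05, camera adjusted p = 0.00286, adjusted p = 0.182 with an estimated correlation), although its median was 0.01 on TPM (-0.05 relative to the other genes). Large falls were those of GDF15 (-5.26 ± 0.36), SESN2 (-3.18 ± 0.07), GADD45A (-1.77 ± 0.06) and CDKN1A (-0.91 ± 0.06). The median of the list was -0.03 without untreated replicate 1, 0.03 without treated replicate 2 and -0.01 without treated replicate 3. Adjusted over the list alone, the counts of members were the same for the called lists of Hth83 except that 41 rose and 0 fell among mitosis and G2/M, 29 rose and 4 fell among double-strand break repair and 15 rose and 3 fell among cholesterol biosynthesis.

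GDF15, a stress-induced cytokine (ENSG00000130513.7, chromosome 19, 18374731 to 18389176, plus strand), fell most among the genes above 10 CPM in Hth83, from 96.4 ± 29.8 to 2.49 ± 0.487 CPM (log2 fold change -5.26 ± 0.36, adjusted p = 0.000289). Other large falls were in the immune receptor OSCAR (-3.42 ± 0.25) and in KLHDC7B (-3.59 ± 0.20). Large rises were in FAM111B (2.07 ± 0.07), a replication-associated protease, the transcription factor E2F2 (2.09 ± 0.10), the carboxypeptidase CPA4 (2.08 ± 0.09), the apelin gene APLN (2.19 ± 0.15), ZNF488 (2.70 ± 0.17) and the triglyceride synthesis enzyme DGAT2 (1.94 ± 0.15). Of the 26 fixed genes, 25 were tested in Hth83, and 13 rose, 9 fell and 3 did not pass, with the same counts adjusted over the list alone. SLC7A11 fell from 727 ± 36.7 to 196 ± 17.2 CPM (-1.89 ± 0.05) and TXNRD1 (-0.42 ± 0.05), EGR1 (-0.83 ± 0.11) and FOS (-0.51 ± 0.14) fell. NQO1 (0.62 ± 0.06), B2M (0.29 ± 0.04) and CCNB1 (0.76 ± 0.05) rose. CD274 (0.39 ± 0.13) had an adjusted p of 0.0657 without untreated replicate 3, and HMOX1 (0.57 ± 0.22) had a log2 fold change of 0.46 (adjusted p = 0.14) without untreated replicate 2 and 0.36 (adjusted p = 0.222) without treated replicate 2. IL6 (1.44 ± 0.40) and FOS lost their calls on log2(TPM + 1), at adjusted p of 0.0681 and 0.0819, as did HMOX1 (0.0909), and FOS also in the joint fit (0.0672). Over all alternatives the adjusted p ran from 0.00254 to 0.0657 for CD274, 0.00713 to 0.222 for HMOX1, 0.000164 to 0.143 for IL6 and 9.54e-10 to 0.159 for FOS.

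By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8657 of 17279 genes tested in Hth83 passed, 4477 higher and 4180 lower. Of those, 1390 differed by at least 2-fold (565 higher and 825 lower), and the median size of the log2 change among all that passed was 0.46. Camera called 12 of 36 lists in Hth83, 7 higher and 5 lower, and 2 of the calls, those of the endoplasmic reticulum and ATF4 lists, held with an estimated correlation, while fry called 28. Camera did not call the other 24 lists tested in Hth83, the closest of which had an adjusted p of 0.0643. Among them were NRF2 targets (0.07), antioxidant enzymes (0.26), MHC class I antigen presentation (0.26), immune checkpoint ligands (0.36), NF-kB driven inflammatory genes (0.16), immediate early genes (-0.10), base and nucleotide excision repair (0.04) and BCL2 family and caspases (0.39), with the median in parentheses. The rest included ferroptosis regulators (0.17), autophagy and lysosome (0.02), fatty acid synthesis (0.03), hypoxia and glycolysis (0), oxidative phosphorylation (0.11), metallothioneins (0.57), platinum and drug transport (0.11) and epithelial-mesenchymal transition and matrix genes (0.12). They also included epithelial junctions (-0.38), YAP and TEAD targets (0.22), keratinocyte differentiation (-0.08), melanocyte markers (-0.19), thyroid follicle markers (-0.01), fibroblast markers (0.54), leukocyte markers (-0.51) and endothelial markers (0.43). Of these, the median, the mean and the test did not share a sign for NRF2 targets, ferroptosis regulators, autophagy and lysosome, epithelial-mesenchymal transition and matrix genes and thyroid follicle markers. Among the uncalled lists, immediate early genes passed without treated replicate 2 (adjusted p = 0.0427) and oxidative phosphorylation, as higher, with library size only (0.0449), with ranges over the camera alternatives of 0.0427 to 0.686 and 0.0449 to 0.524. The p53 list was at 0 after a trend with gene length and GC was removed.

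**Figure D3:**
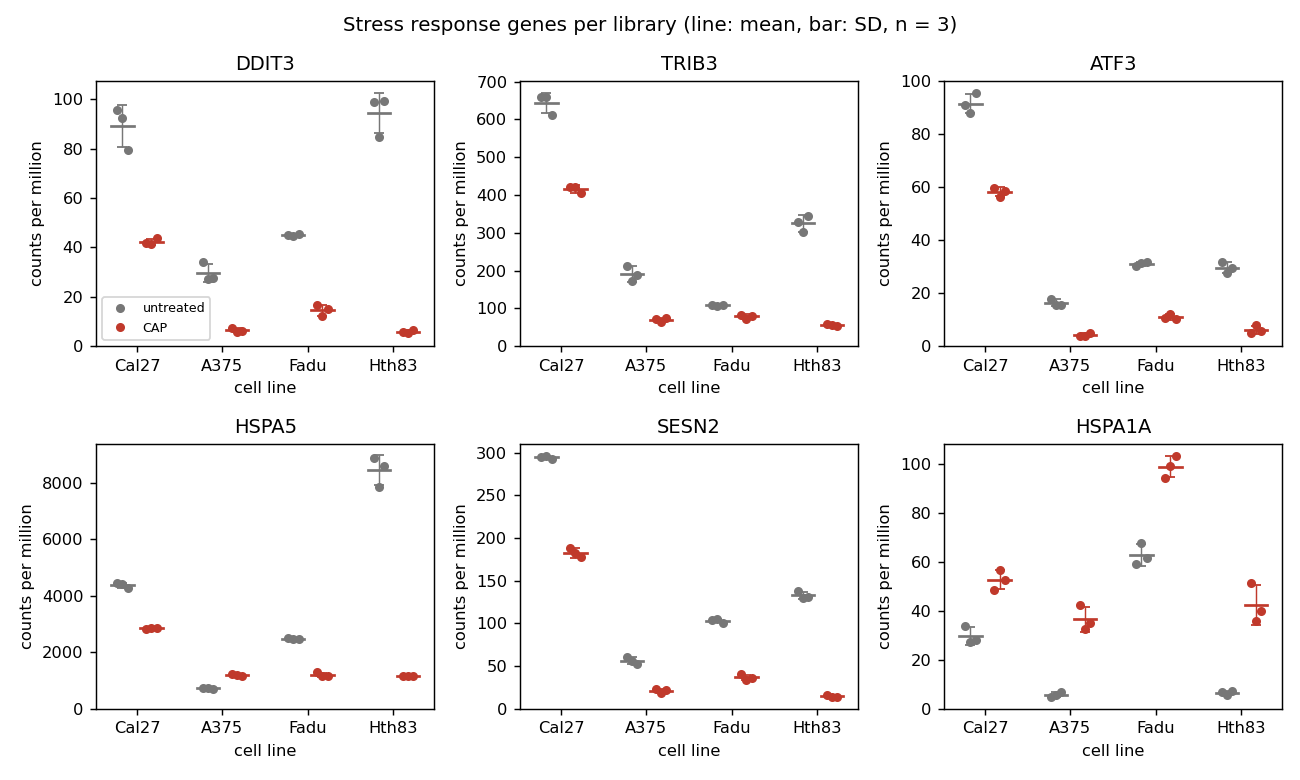
CPM of 6 stress response genes in each library, untreated in grey and plasma-treated in red, with a horizontal line at the mean and a bar for the SD (n = 3). DDIT3, TRIB3, ATF3 and SESN2 were lower after plasma in every line, whereas HSPA5 was higher in A375 and lower in the other 3 lines.

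A fit of all 24 libraries asked which genes changed on average over the 4 lines. SESN2, a stress-induced regulator of nutrient signalling, had a mean log2 fold change of -1.71 ± 0.03 (adjusted p = 8.1e-38) and fell in each line (-0.70 in Cal27, -1.45 in A375, -1.48 in Fadu and -3.19 in Hth83). The amino acid response genes PCK2 (-1.21 ± 0.03), AARS1 (-0.74 ± 0.02) and SLC38A2 (-0.70 ± 0.02), the EGFR inhibitor ERRFI1 (-0.78 ± 0.02) and the transcriptional cofactor LMO4 (-0.99 ± 0.03) also fell on average and in each line. The chaperone HSPH1 (0.72 ± 0.02), the chromatin protein HMGA2 (0.72 ± 0.02) and FAM111B (1.13 ± 0.03) rose on average and in each line, HMGA2 by 2.23 in Fadu and by at most 0.27 in the others. HSPA5 had the smallest p of this test (-0.96 ± 0.02, adjusted p = 4.66e-40) although it rose in A375. On the deposited TPM of Cal27, AARS1, SLC38A2 and PCK2 stood at -0.02 (adjusted p = 0.572), -0.01 (0.89) and -0.11 (0.161) and missed the threshold, with ranges over all alternatives of 5.44e-15 to 0.625, 1.13e-11 to 0.933 and 4.94e-13 to 0.262. DDIT3, TRIB3, ATF3 and GDF15 were the genes of the fixed panel that fell in all 4 lines, and 19, 25, 25 and 25 members of the ATF4 list fell in Cal27, A375, Fadu and Hth83. Of 23642 genes tested, 9188 passed for the mean of the lines, 4861 higher and 4327 lower, but only 2542 of them had the same sign in all 4 lines, and 192 genes rose and 184 fell in all 4 lines tested separately.

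The response differed between the lines, by a test of the line by treatment interaction. HSPA5 had the smallest p of this test (adjusted p = 9.87e-44), with log2 fold changes of -0.62 in Cal27, 0.68 in A375, -1.03 in Fadu and -2.89 in Hth83, and its partner chaperone HYOU1 differed likewise, -0.31 in Cal27, 0.41 in A375, -0.51 in Fadu and -1.61 in Hth83. FST fell in Cal27 and rose in Fadu (-1.98 in Cal27, 0.27 in A375, 2.27 in Fadu and -0.21 in Hth83), IL1RL1 rose in Fadu and fell in Hth83 (4.67 and -2.40), and the EGFR ligand AREG fell in Cal27 and Hth83 and rose in A375 and Fadu (-1.36 in Cal27, 0.89 in A375, 0.54 in Fadu and -2.18 in Hth83). ARRDC4 (0.08 in Cal27, -1.17 in A375, 3.49 in Fadu and 0.52 in Hth83), UPP1 (-0.56 in Cal27, -0.09 in A375, 1.56 in Fadu and -0.81 in Hth83), GTPBP2 (-0.39 in Cal27, -0.71 in A375, 0.20 in Fadu and -2.03 in Hth83), HMGA2 and MMP1 (2.01 in Fadu and -0.44 in Hth83) completed the 10 genes of smallest p. On TPM, HYOU1 in Cal27 was at -0.07 (adjusted p = 0.124), and FST in A375 and Hth83 lost its calls (0.062 and 0.109), with ranges over all alternatives of 2e-13 to 0.208, 4.3e-14 to 0.12 and 3.65e-05 to 0.247. By camera, the interferon list differed between Fadu and Hth83 (median difference -1.40) and the NRF2 list between Cal27 and Fadu (1.16). The endoplasmic reticulum list differed between A375 and Hth83 (1.85). Each difference also passed with an estimated correlation, with p-values given below. Of 216 tests of a list between a pair of lines, 98 passed and 62 with an estimated correlation. The interaction passed for 13457 of 23642 genes (56.9%). Of 11072 genes passing in 2 or more lines, 6736 (60.8%) had opposite signs, untested against chance.

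**Figure D4:**
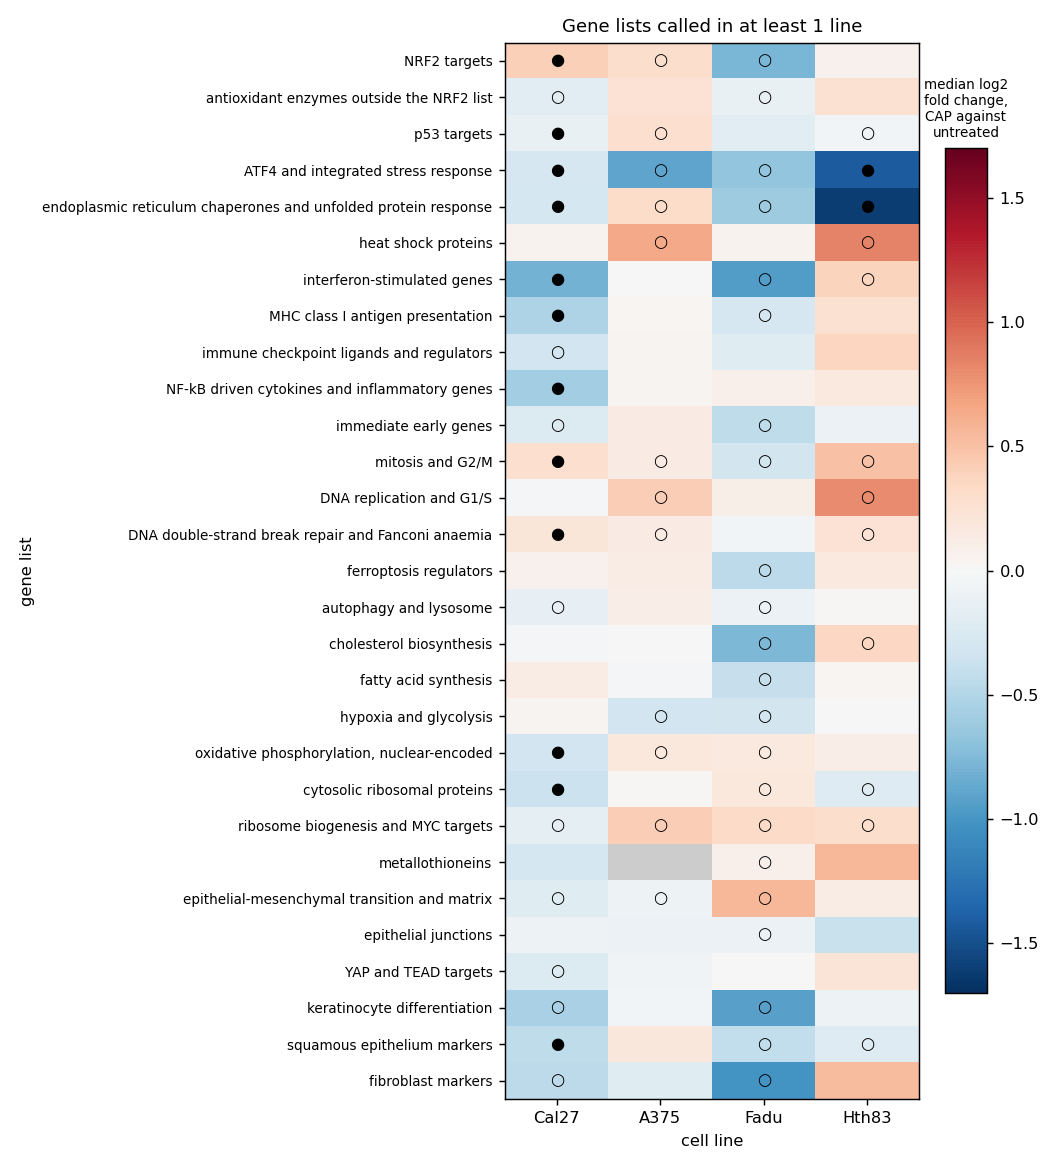
Median log2 fold change of the members of each gene list called in at least 1 line, plasma-treated against untreated, in red where higher and blue where lower. An open circle marks a camera call, a filled circle a call that also held with an estimated correlation, and grey a list with too few tested members. Small Cal27 medians turn positive on TPM for the p53, antioxidant, immediate early, autophagy and ribosome biogenesis lists, as do the Fadu median of epithelial junctions with library size only and the Hth83 median of p53 targets on TPM, while each stays below the median of the other genes.

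The overlap of the genes that passed asked whether the lines responded through the same genes. A375 and Hth83 had more genes in common in both directions than independent lists would: 2475 against 1293 by independence, odds ratio 5.47, for genes higher in both. The genes lower in both were 1611 against 935 by independence, odds ratio 3.14 (adjusted p = 6.14e-173, two-sided Fisher's exact test). Fadu shared genes with Hth83 (1733 against 1266 by independence, odds ratio 1.98, higher in both) and with A375 (1923 against 1351 by independence, odds ratio 2.2, higher in both). Over all genes that passed, Cal27 and Fadu overlapped more in opposite directions than in the same direction, 1663 against 1090 by independence, odds ratio 2.47 (adjusted p = 8.41e-116), for genes higher in Cal27 and lower in Fadu. For the reverse it was 1731 against 1137 by independence, odds ratio 2.48 (adjusted p = 1.36e-120). Genes higher in both were 834 against 1072 by independence, odds ratio 0.65. Across genes, log2 fold changes followed gene length and GC content in opposite directions in these lines, with a Spearman correlation of 0.21 and -0.31 in Cal27 and -0.18 and 0.15 in Fadu. Among genes changed at least 2-fold the picture was another: the excess of genes higher in Cal27 and lower in Fadu missed the threshold (odds ratio 1.28, adjusted p = 0.352) and that of the reverse passed (2.94, adjusted p = 0.00053). Of these, genes higher in both had an odds ratio of 1.46 (adjusted p = 0.127) and genes lower in both of 12.37 (adjusted p = 1.54e-29), against 0.84 for all that were lower in both. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.35 (Pearson) for A375 and Hth83 and 0.01 for Cal27 and Fadu.

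Cal27 also overlapped with the 2 other lines. Genes lower in Cal27 and higher in A375 were 1702 against 1149 by independence, odds ratio 2.36 (adjusted p = 3.25e-106), whereas genes lower in both were 799 against 932 by independence, odds ratio 0.77, genes higher in both 1226 against 1115 by independence, odds ratio 1.2 and genes higher in Cal27 and lower in A375 926 against 904 by independence, odds ratio 1.04 (adjusted p = 0.362). Among genes changed at least 2-fold, those lower in Cal27 and higher in A375 missed the threshold (odds ratio 2.75, adjusted p = 0.0812), while those lower in both (4.62, adjusted p = 2.9e-06), higher in both (3.27, adjusted p = 0.000431) and higher in Cal27 and lower in A375 (1.76, adjusted p = 0.028) passed. Cal27 and Hth83 shared genes higher in both (1213 against 1013 by independence, odds ratio 1.42), lower in both (1202 against 965 by independence, odds ratio 1.52) and lower in Cal27 but higher in Hth83 (1271 against 1060 by independence, odds ratio 1.43). Genes higher in Cal27 and lower in Hth83 were 924 against 923 by independence, odds ratio 1 (adjusted p = 0.965), but passed among genes changed at least 2-fold (odds ratio 2.39, adjusted p = 0.000122), as did the other 3 combinations, with odds ratios of 1.94, 6.1 and 3.02. The lines share no control libraries.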

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

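The tests of gene length and GC, of scaling, of the glucose-responsive genes and of other splits of the libraries were chosen or written out only after the results were seen, whereas the tests between lines were set earlier. The treatment effect differed between the 4 lines, by a test of the difference itself, for 13457 genes. By pair, it differed for 8383 genes between Cal27 and A375, 9070 between Cal27 and Fadu, 8272 between Cal27 and Hth83, 8502 between A375 and Fadu, 6453 between A375 and Hth83 and 8430 between Fadu and Hth83. Contrasts with Fadu, alone in MEM, do not separate line from medium. Among the panel, 17 genes passed in opposite directions in 2 lines with an interaction that also passed, CD274 and CXCL8 among them.

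In 22 combinations of a list and a pair of lines, over 10 lists, the list was called in opposite directions and the difference passed, in 19 of them also with an estimated correlation, although in no combination did the calls of both lines hold with it. The median difference of log2 fold changes was -1.40 (adjusted p = 4.31e-19, 0.002 with an estimated correlation) for interferon-stimulated genes in Fadu minus Hth83 and 1.16 (adjusted p = 5.16e-20, 0.00269 with an estimated correlation) for NRF2 targets in Cal27 minus Fadu. It was 1.85 (adjusted p = 2.21e-56, 0.000178 with an estimated correlation) for endoplasmic reticulum genes in A375 minus Hth83, -1.03 (adjusted p = 2.12e-17, 0.00269 with an estimated correlation) for cholesterol synthesis and -0.71 (adjusted p = 6.11e-30, 0.00269 with an estimated correlation) for mitosis in Fadu minus Hth83. For cytosolic ribosomal proteins in Cal27 minus Fadu it was -0.53 (adjusted p = 4.92e-28, 0.0168 with an estimated correlation), and in Cal27 minus A375 it was -0.49 (adjusted p = 1.54e-19, 0.002 with an estimated correlation) for oxidative phosphorylation and -0.54 (adjusted p = 4.84e-16, 0.0301 with an estimated correlation) for ribosome biogenesis.

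The ATF4 list, the target genes of amino acid and endoplasmic reticulum stress, was lower in all 4 lines by camera at its preset correlation, and with an estimated correlation the calls of A375 (adjusted p = 0.199) and Fadu (0.0926) were lost. A trend with gene length and GC does not account for it, since the median nearest to 0 after the trend was removed was -0.24 (Cal27, interval -0.40 to -0.11). Over 4 scalings the list's own median nearest to 0 was -0.57 in A375, Fadu and Hth83 (interval -0.73 to -0.50, Fadu with library size only), so these scalings do not account for the fall there, and -0.06 in Cal27 (interval -0.19 to 0.08, on TPM), where fall and scaling cannot be told apart, although a factor per library leaves a list's distance from the other genes as it is. More glucose left in treated wells was read only from the glucose-responsive TXNIP and ARRDC4. In A375 their fall (TXNIP at -3.51) only argues against it. They cannot tell in Cal27 (TXNIP at -0.28 but ARRDC4 at 0.32 on TPM). Glucose may contribute in Fadu and Hth83, where both rose with every scaling (TXNIP at 1.51 in Hth83). A lasting effect of plasma on the cells stays open as an untested explanation, as does a difference in cell density at harvest, which the labels do not give.

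The interferon list was lower in Cal27 and Fadu by camera at its preset correlation, and the call of Fadu was lost with an estimated correlation (adjusted p = 0.0938). The median nearest to 0 was -0.90 after the length and GC trend was removed and -0.56 over 4 scalings (interval -0.78 to -0.40, Cal27 on TPM), so neither the trend nor these scalings account for it. An effect of plasma that differs between lines may remain as a hypothesis, found and tested on the same libraries, and batch or density differences between the wells of a line were not recorded and stay open.

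The ribosomal protein and oxidative phosphorylation lists were lower in Cal27, by a small amount. The median nearest to 0 was -0.33 after the trend was removed, although fold changes in Cal27 followed length (Spearman 0.21) and GC (-0.31) across genes. Over 4 scalings it was -0.08 for oxidative phosphorylation (interval -0.12 to -0.03) and -0.14 for ribosomal proteins (interval -0.16 to -0.08), both on TPM. The sign held, so neither the trend nor these scalings account for the fall. Its size stays open, as TPM moved the median of all Cal27 genes by 0.224. Reads shared with ribosomal protein pseudogenes were not analysed, and a biological change stays a hypothesis.

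Splitting the 6 libraries of a line 3 against 3 in all 10 ways cannot give a share under 0.05. The treatment split gave 7832, 9900, 10200 and 8657 genes in Cal27, A375, Fadu and Hth83, and the highest of the other splits gave 0 in each line by edgeR, with at most 347, 237, 214 and 229 genes at an unadjusted p under 0.05. For gene lists, the treatment split gave 21, 12, 22 and 12, and the highest other split 11, 13, 14 and 10. In A375, 2 of 10 splits, the real one included, gave as many lists, and in each of the other lines 1 of 10, so camera at its preset correlation calls lists in splits that mix the arms. Such splits keep part of the treatment contrast, so their list calls need not be false. For the joint tests, 1 of 40 drawn splits, the real one, gave as many genes. The interaction gave 13457 against at most 1484 and the mean 9188 against at most 416. The other splits mix the arms, so chance stays open.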

How the results depend on the processing

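The tests after removing a trend with gene length and GC, and the list medians under other scalings, were chosen only after the results were seen. Requiring at least a 2-fold change left 617, 1385, 1814 and 1390 genes in Cal27, A375, Fadu and Hth83, by construction. Limma on log2(TPM + 1) without a filter called 6057 genes in A375, and the cause was not tested. Camera with an estimated correlation called 12, 0, 0 and 2 lists, and the cause was not tested (where it called 0, camera at its preset correlation called 12 in A375 and 22 in Fadu, 5 and 14 had an unadjusted p under 0.05 with an estimated correlation and fry called 22 and 32), and fry called 22 in A375 and 28 in Hth83, since it does not compare a list with other genes. CCNB1 in Fadu was not called (-0.01, adjusted p = 0.79) and passed with library size only (0.09, adjusted p = 0.00662), which moved the median of all Fadu genes by 0.105, with a range over all alternatives of 0.00662 to 1.

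Leaving out a library gave 6956 to 7820 genes in Cal27, 8739 to 9676 in A375, 9431 to 9737 in Fadu and 7792 to 8506 in Hth83, 21 to 23, 11 to 12, 21 to 22 and 12 to 13 lists, 13075 to 13382 genes for the interaction and 8893 to 9164 for the mean over lines. A replicate block gave 7704, 9946, 10183 and 8652 genes and, of the list calls, changed those of epithelial-mesenchymal transition and matrix genes in A375 (adjusted p = 0.0645) and antioxidant enzymes in Fadu (0.0582), which were lost, and of the BCL2 list in Cal27 (0.041), which was gained, and no other call of a list or a named gene. The labels pair no libraries, and the 12 same-numbered pairs correlated at -0.14 to 0.1. Among named genes and alternatives, 5543 values kept their side of the threshold and direction, 73 lost a call, 22 gained one and 1 changed sign and gained a call, and among lists 1725, 71, 60 and 0. On TPM, 57% of the genes called in Cal27 were called again, 4361 of these 4468 genes in the same direction and the others in the opposite one. At these depths 1.2-fold changes were often missed in simulations, in which far fewer genes changed than passed in the data.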

Other observations

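The genes in this paragraph were chosen only after their values were seen, as were the tests of the glucose-responsive genes. TXNIP and ARRDC4, arrestin-like proteins that restrain glucose uptake and whose transcription rises with glucose, moved in parallel in A375, Fadu and Hth83 and in different directions between the lines. Fadu alone was in MEM. TXNIP was at -3.51 in A375, 4.14 in Fadu, 1.51 in Hth83 and -0.28 in Cal27, where it missed the threshold on TPM (-0.05, adjusted p = 0.506). ARRDC4 was at -1.15 in A375, 3.48 in Fadu and 0.54 in Hth83, each with an adjusted p under its threshold in edgeR, and at 0.08 in Cal27 (adjusted p = 0.0852), where it rose with library size only (0.17) and on TPM (0.32).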
